A study of Mus musculus with 10 samples.

How the data were processed

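The data are RNA-seq libraries from mouse B cell preparations of bone and spleen, 10 in all. Per the labels' protocols, RNA was extracted with the miRNeasy kit and libraries were made from 500 ng of total RNA with the TruSeq Stranded Total RNA kit, which depletes ribosomal RNA and marks the strand of each read. The authors deposited 1 table of raw counts, whole numbers of reads per gene, not normalised. Per the submitters' processing notes, the tools were STAR 2.4.0a for alignment and featureCounts from Subread 1.4.6-p1 for counting, and the genome build was mm10, which is GRCm38. The strand setting and the treatment of reads that match more than 1 place are not given in the sources used here. Counts of pseudogenes, of immunoglobulin segments that resemble each other, of other gene families and of genes that overlap on opposite strands are therefore uncertain.

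The deposited count table holds 46959 genes and 100 further entries for spike-in and phiX sequences, which summed to between 1 and 17 counts per library and were left out of library sizes and tests. Coordinates are those of the deposited table, in mm10. Gene classes such as pseudogene or protein-coding were taken from GENCODE M21, whose symbols matched 44217 genes (94.16%). Total counts ran from 18614742 to 29314068 per library. A count of 0 was taken to allow up to 3 counts over a group, and a fold against a group at 0 was computed against those 3 counts and is given as a lower bound. Such limits cover counting error only, and the reads carry no molecular identifiers. Intervals of odds ratios, shares and ratios are over genes.

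Samples were placed in 6 groups by their labels. The 4 femoral libraries were pools of 3 mice each: 2 from RAG2 and gamma c deficient mice (control), 1 from KOKI mice on that background and 1 from KOKI mice deficient for RAG2 alone. The 6 splenic libraries were 2 wild-type (WT) cultures with LPS, 2 WT cultures with LPS and SAHA and 2 KOKI cultures. The labels do not spell out KOKI. The title and the series' design text give the KOKI cultures as treated with LPS, while their treatment label names LPS and SAHA; the group was taken from title and design text, and the KOKI cultures were also compared with WT LPS+SAHA. Names of the SAHA libraries contain "D3", while the protocol gives 2 days of culture. The design text speaks of 2 pools for each of 3 femoral genotypes, and the 4 femoral libraries fall into groups of 2, 1 and 1. Nothing in the labels says that replicates of the splenic cultures came from separate animals, apart from the numbers in the titles, so p-values measure only the spread between these samples, which may be technical in part. Pairs of libraries were compared before averaging. Over genes with at least 20 counts the chi-square per degree of freedom was 92.6 to 161 within the 4 groups of 2 and 44.1 between the femoral KOKI pools, so none of these 5 pairs were copies.

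Tests were made with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), and the quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The SAHA and the splenic KOKI comparison came from 1 fit of the 6 splenic libraries in 3 groups. The femoral KOKI comparison came from the 4 femoral libraries, both KOKI libraries against both controls. The comparison on the matched background, the difference between the femoral KOKI libraries and the test of spleen against femur came from all 10 libraries in 6 groups. In these, a lone library was assumed to vary like the other groups. CPM values were computed here from the deposited counts with edgeR and TMM library sizes unless a summed or per-library CPM is named, which used plain totals. Log2 fold changes are given with their standard error (SE), and CPM as mean ± SD.

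Immunoglobulin V, D and J segments were summed per locus, and the sums replaced the single segments in a further fit of the same design. P-values of heavy chain features were adjusted over all features and over the heavy chain features alone. A set of 30 gene lists, for pathways, cell types and the surroundings of the heavy chain locus, was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, which asks whether a list's genes move 1 way on balance (or, in its mixed form, either way). Lists with at least 5 tested members entered, 25 for each splenic comparison and 27 for the femoral one, and p-values were adjusted over lists. Beside counts over all genes, counts "adjusted over the list alone" use only a list's members. Fisher's exact test (two-sided) compared called genes within 10 Mb of the heavy chain locus with all others.

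The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per main comparison, the 10 largest rises and the 10 largest falls among called genes in which every library of 1 group lay above every library of the other and the higher group had a mean of at least 10 CPM, leaving out immunoglobulin segments, ribosomal RNA and predicted genes. Where none passed, the 5 genes with the smallest p were taken. To these came the heavy chain constant genes, Rag2, Il2rg, Prdm1, Xbp1, Irf4, Pax5 and Bach2, up to 4 members of each list with the smallest p, and up to 3 single segments per class where any passed. The text names a part of these genes. Gm13225 and Gm13160 fall outside the rule and were chosen after their values were seen.

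The 3 main edgeR comparisons, and camera with its preset, were first run on simulated counts drawn from the real means and library sizes. For edgeR 200 genes were changed. The other tests were not simulated in this way. In the SAHA design edgeR recovered 71 of 100 genes changed by a log2 fold of 1 and 100 of 100 changed by 2, with 22 false calls among 14754 genes. For the splenic KOKI comparison it recovered 60 and 99 of 100, with 11 false calls among 14740, and for the femoral one 44 and 96 of 100, with 12 false calls among 16140. As a share of the genes called, false calls exceeded the 0.05 that the threshold aims at in each design, most in the SAHA design. Each design was simulated only 1 time. A planted gene list was recovered by camera in each of the 3 designs, with 0 other lists called. Simulated genes were drawn independently, so this does not cover lists whose genes move together.

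The alternatives were DESeq2 1.42.0 size factors within edgeR, the DESeq2 Wald test, normalisation without immunoglobulin genes, no low-count filter beyond 1 count in total, leaving out each library in turn, other sets of libraries in the fit, and the replicate number as a block. The block was fitted to the 4 libraries of each comparison alone. This left 1 residual degree of freedom, so blocked counts are not a firmer result than the main fit. Over genes with a mean log2 CPM of at least 3, deviations of same-numbered WT LPS and WT LPS+SAHA libraries from their group means correlated at 0.51 across 8793 genes. Their titles give the same WT number, read here as the same mouse, so blocked values stand beside the SAHA results given in the text where they change a call or move a count by over 1.5 times. Further alternatives were added after seeing the data: normalisation without ribosomal RNA, 7SK and satellite genes, testing protein-coding genes outside the immunoglobulin loci only, and list members called without WT LPS+SAHA replicate 2 or KOKI replicate 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.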

Results

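RNA was sequenced from 10 mouse B cell preparations. Spleen cells depleted of CD43-positive cells, which leaves mostly resting B cells, were cultured for 2 days in medium with 10% fetal calf serum and 5 µg/ml lipopolysaccharide (LPS), a bacterial product that drives B cells to divide and to become antibody-secreting plasmablasts. Cultures came from wild-type (WT) mice with LPS (n = 2), from WT mice with LPS and 200 ng/ml SAHA (n = 2) and from KOKI mice (n = 2). SAHA, or vorinostat, inhibits histone deacetylases (HDACs), enzymes that remove acetyl groups from histones. Cells labelled femoral B cells came from mice that lack RAG2, without which antigen receptor genes are not rearranged, and gamma c, the shared receptor chain of several interleukins encoded by Il2rg. These were 2 control pools, 1 pool of KOKI mice lacking both proteins and 1 pool of KOKI mice lacking RAG2 alone, each of 3 mice. The series asks how HDAC inhibitors and the regulatory region downstream of the immunoglobulin heavy chain (IgH) genes bear on transcription of the IgH locus. Total counts ran from 18614742 in KOKI LPS replicate 2 to 29314068 in femoral control replicate 2.

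Transcripts of Rag2 and Il2rg were present in every femoral library. Rag2 stood at 9.16 and 6.93 CPM in the controls, 7.24 CPM in the KOKI pool lacking both proteins and 9.32 CPM in the KOKI pool lacking RAG2 alone. Il2rg stood at 12.3, 8.12, 10.2 and 11.4 CPM in the same order, and at 43.2 to 58.2 CPM in the splenic libraries. The labels do not say which part of either gene was deleted, and counts summed over a whole gene do not check the deletion.

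The femoral libraries held little mature B cell RNA and much RNA of other blood lineages. Ms4a1 (CD20) reached at most 0.0946 CPM in them, against at least 858 CPM in every splenic library. Summed over all members, neutrophil markers took 14300 to 21600 CPM of the femoral libraries and 1.06 to 4.71 CPM of the splenic ones, erythroid markers 10200 to 13300 against 7.17 to 23.2 CPM, and mast cell and basophil markers 1730 to 2090 against 0.575 to 2.48 CPM. A large part of the last sum was Prg2, an eosinophil granule protein, at 751 to 1380 TMM-normalised CPM in the femoral libraries. Early B cell genes overlapped, at 1140 to 2040 against 1060 to 2420 CPM, with Cd24a alone giving 429 to 1270 CPM in the femoral libraries. Dntt, the enzyme that adds bases at joints of rearranged receptor genes, was at 40.2 to 58.1 CPM in the femoral libraries and at most 0.152 CPM in the splenic ones.

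**Figure D1:**
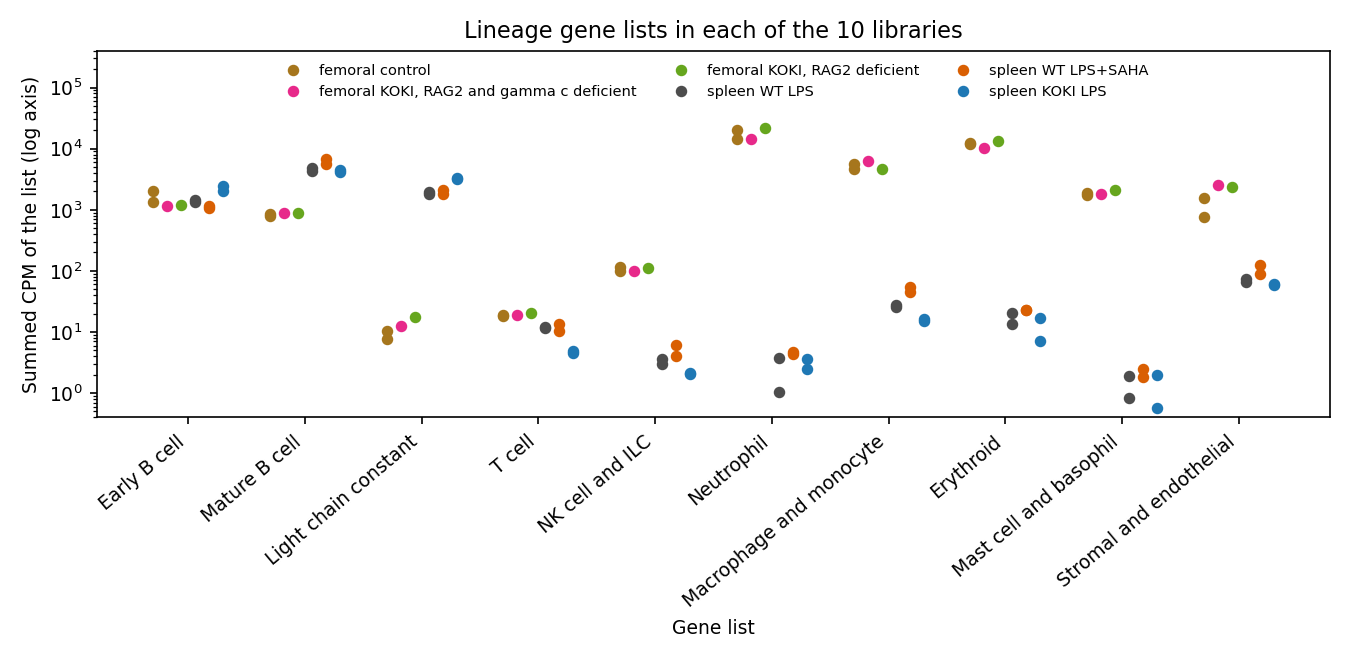
Summed CPM (log axis) of 10 lineage gene lists, 1 point per library, coloured by group. Neutrophil, erythroid, macrophage and mast cell lists lie far higher in the 4 femoral libraries, and mature B cell and light chain constant genes higher in the 6 splenic ones.

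With SAHA most cell cycle genes and parts of the unfolded protein response and plasmablast lists were lower in WT LPS cultures, and part of the mature B cell genes was higher. Among 15342 genes tested, 146 rose and 566 fell (edgeR, adjusted p under 0.05), and 153 of these 712 changed by a log2 fold of at least 1 in size. Prdm1 (chromosome 10, 44437177 to 44528501), which encodes Blimp-1, the regulator that drives B cells to plasma cells, fell from 29.9 ± 1.12 to 11.2 ± 0.0178 CPM (log2 −1.42, SE 0.13, edgeR adjusted p = 0.0185, n = 2 in each group). Xbp1, a regulator of the secretory machinery, fell from 102 to 51.6 CPM (log2 −0.98, edgeR adjusted p = 0.025). Cr2 (chromosome 1, 195136811 to 195176716), the complement receptor CD21, rose from 118 ± 1.05 to 279 ± 6.18 CPM (log2 1.24, SE 0.15, edgeR adjusted p = 0.0186, n = 2 in each group). With the WT number as a block 3413 genes passed (1240 higher, 2173 lower), in a fit of the 4 compared libraries alone with 1 residual degree of freedom. The DESeq2 Wald test called 1721 (557 and 1164), the test without a low-count filter 1970, and protein-coding genes outside the immunoglobulin loci gave 1346 (521 and 825). In edgeR the call was lost entirely (0 genes) without WT LPS replicate 1, without WT LPS+SAHA replicate 1 or 2, and in a fit of the 4 compared libraries alone, with 2650, 2973, 3136 and 3765 genes at an unadjusted p under 0.05. Without WT LPS replicate 2 it was 290, without KOKI replicate 1 or 2 it was 155 and 211, and with all 10 libraries 211 (68 higher, 143 lower).

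Of 34 cell cycle genes tested, 25 fell, 0 rose and 9 did not pass, and adjusted over the list alone 32 fell. Cyclin B1 (Ccnb1) went from 226 ± 9.87 to 90.6 ± 3.94 CPM (log2 −1.32), the mitotic kinase Cdk1 from 160 to 69.4 CPM (log2 −1.20) and the kinase Aurka from 40.8 to 17.8 CPM (log2 −1.20), each at an edgeR adjusted p of 0.0185. The list as a whole was lower than other genes (camera adjusted p = 2.46e-35, and adjusted p = 0.119 with an estimated correlation). Cdc20, which activates the complex that ends mitosis, fell too (log2 −1.36).

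Part of the mature B cell genes was higher. Of 25 tested, 5 rose, 0 fell and 20 did not pass. Adjusted over the list alone 12 rose, and 16 did so with the WT number as a block (camera adjusted p = 9.47e-09, and adjusted p = 0.371 with an estimated correlation). Besides Cr2 these included Fcer2a, the low-affinity IgE receptor CD23, from 70.7 to 161 CPM (log2 1.19), Bcl6, a repressor of the plasma cell programme, from 13.8 to 31.0 CPM (log2 1.16), and Fcmr, the IgM Fc receptor (log2 0.91). Markers of macrophages and monocytes moved the same way. All 8 tested members had a positive log2 fold change and 1, Adgre1 (F4/80), passed at log2 0.92 (adjusted over the list alone 2 rose, and 2 of 7 with the block; camera adjusted p = 0.0347, and adjusted p = 0.371 with an estimated correlation). Their sum was 45.5 and 55.2 CPM in the SAHA libraries and 25.5 and 27.3 CPM in the WT LPS libraries.

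Part of the genes of the unfolded protein response, which adjusts the capacity to fold secreted proteins, was lower. Of 20 tested, 5 fell and 0 rose, and 16 fell adjusted over the list alone or with the WT number as a block (camera adjusted p = 1.85e-08, and adjusted p = 0.18 with an estimated correlation). Chac1, a glutathione-degrading enzyme induced by this response, had the largest fall of the genes named (log2 −2.13, from 10.3 to 2.34 CPM). Manf fell by 0.83 and Pdia6 by 0.75 on the log2 scale. Asns, asparagine synthetase, fell from 77.0 to 29.1 CPM (log2 −1.40), and Slc7a3, a carrier of basic amino acids, from 27.5 to 9.12 CPM (log2 −1.59). Of 19 plasmablast genes, 3 fell (Prdm1, Xbp1 and the elongation factor Ell2, log2 −0.64) and 1, the transcription factor Zbtb20, rose (log2 0.69). Adjusted over the list alone 1 rose and 5 fell, and 1 rose and 8 fell with the block (camera adjusted p = 0.00272, and adjusted p = 0.251 with an estimated correlation).

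Among class switch recombination genes 2 of 28 fell, the exonuclease Exo1 (log2 −0.73) and the endonuclease Apex1 (log2 −0.67), and adjusted over the list alone 1 rose and 11 fell (camera adjusted p = 0.00135, and adjusted p = 0.209 with an estimated correlation). With the block 1 rose and 13 fell. Cholesterol synthesis had 3 falls among 21 genes (Idi1, log2 −1.02, Hmgcs1, log2 −0.79, and Insig1, log2 −0.71), 7 adjusted over the list alone and 10 with the block (camera adjusted p = 0.00215, and adjusted p = 0.718 with an estimated correlation). Glycolysis had 2 falls among 19 (the lactate carrier Slc16a1, log2 −1.03, and Pgam1, log2 −0.72), 4 adjusted over the list alone and 11 among 18 with the block (camera adjusted p = 0.0236, and adjusted p = 0.878 with an estimated correlation). No interferon response gene of 25 passed (0 also adjusted over the list alone), although the list was lower (camera adjusted p = 0.00272, and adjusted p = 0.371 with an estimated correlation). With the block 8 fell.

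Genes often raised by HDAC inhibitors split. Of 12 tested, 2 rose: Gsn, the actin-severing protein gelsolin, from 11.8 ± 2.53 to 34.4 ± 0.665 CPM (log2 1.54, SE 0.20, edgeR adjusted p = 0.0216, n = 2 in each group), and Txnip, the thioredoxin inhibitor (log2 0.70). Adjusted over the list alone or with the block 2 rose and 2 fell, the median log2 fold change was −0.15, and the list did not pass (camera adjusted p = 0.958, direction up, against the sign of the median). Of the 11 HDAC genes none passed by edgeR, with Hdac2 at log2 −0.44 (adjusted p = 0.0782; adjusted p = 0.0171 with the block) and 0 passing adjusted over the list alone (camera adjusted p = 0.525). With the block 1 of the 11 rose and 1, Hdac2, fell. Of 22 genes of Polycomb and related silencing complexes, 4 fell, among them Suz12, a core subunit of Polycomb complex PRC2 (log2 −0.73), Bmi1 (log2 −0.56) and Uhrf1 (log2 −0.73), and Cbx7 rose (log2 0.78). The counts were the same adjusted over the list alone, and 2 rose and 8 fell with the block (camera adjusted p = 0.473). NF-kB response genes went both ways, with Tnf up (log2 1.14) and Il10 (log2 −1.27) and Ccl22 (log2 −0.78) down among 24, also adjusted over the list alone (camera adjusted p = 0.975), and 2 rose and 2 fell with the block. Without WT LPS+SAHA replicate 2, in which counts fell on 451 of 1292 olfactory receptor genes against 126 in replicate 1 and 46 and 47 in the WT LPS libraries, 0 members of any list passed in edgeR. Median log2 fold changes without it went from −0.91 to −0.96 for cell cycle, from 0.44 to 0.45 for mature B cell and from −0.61 to −0.66 for unfolded protein response genes. They moved further for Polycomb and silencing genes (−0.07 to −0.22), HDAC inhibitor markers (−0.15 to −0.30) and light chain constant genes (0.30 to 0.68). Of the 25 lists, 9 passed with the preset and 0 with an estimated correlation (fry called 9 for 1 direction and 21 mixed), and with the block MHC class II passed as well (adjusted p = 0.048, 0.0941 without it).

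**Figure D2:**
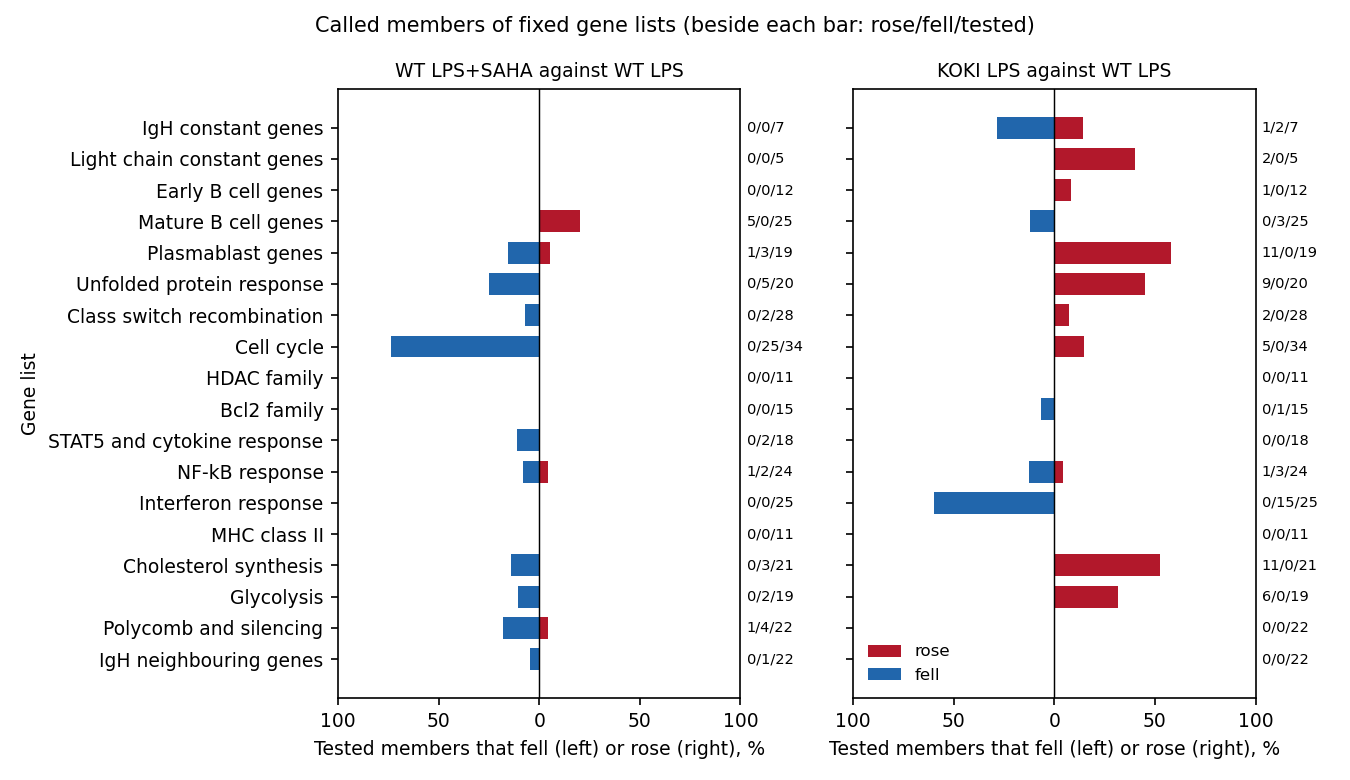
Percent of the tested members of each fixed gene list that rose (right) or fell (left) with SAHA (left panel) and in KOKI cultures (right panel), with counts of rose, fell and tested members beside each bar. Cell cycle genes fell with SAHA (25 of 34), and plasmablast genes rose (11 of 19) and interferon response genes fell (15 of 25) in KOKI cultures.

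The IgH locus spans chromosome 12 from 113254830 (Igha) to 116010093 in the deposited coordinates, with the constant genes at the low end and the V segments beyond them. In WT LPS cultures SAHA moved no IgH constant gene or segment sum past the threshold over all features. Ighm was at 2170 ± 134 CPM with SAHA and 3060 ± 247 CPM without (log2 −0.50, SE 0.21, edgeR adjusted p = 0.179, n = 2 in each group). The summed V segments were at 692 ± 55.9 against 883 ± 27.6 CPM (log2 −0.35, edgeR adjusted p = 0.248, n = 2 in each group), the D segments at log2 0.14 and the J segments at log2 0.36. The sign for D turned (log2 −0.13) without WT LPS replicate 2. Adjusted over the IgH features alone, Ighd (log2 0.69, adjusted p = 0.0368), Ighg2b (log2 −0.56, 0.0374) and Igha (log2 0.83, 0.0374) passed, and all of these passed over all genes with the WT number as a block (adjusted p = 0.00319, 0.0195 and 0.00526). Of 104 V segments tested singly, 1 fell (Ighv7-3, log2 −0.78), with 0 rises. Of 22 genes neighbouring the locus, Ncapg2, a condensin subunit, fell (log2 −0.84), and 3 fell adjusted over the list alone (camera adjusted p = 0.975). With the block 1 rose and 3 fell of 21.

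KOKI cultures differed from WT LPS cultures in plasmablast, interferon and metabolic genes and in several genes seen nearly only in 1 of the genotypes. Of 15342 genes, 345 were higher and 281 lower (edgeR, adjusted p under 0.05), 420 of them by a log2 fold of at least 1 in size. Prdm1 rose from 29.9 ± 1.12 to 79.3 ± 4.54 CPM (log2 1.41, SE 0.12, edgeR adjusted p = 0.000912, n = 2 in each group) and Xbp1 from 102 to 290 CPM (log2 1.51, edgeR adjusted p = 0.00174). Xist, the X-inactivation RNA, had 8499 counts in KOKI replicate 2 and at most 9 in any other splenic library, while the Y-linked Ddx3y had 20 counts there and 3183 to 5868 in the others. The DESeq2 Wald test called 1097 genes, edgeR without a low-count filter 1254, and leaving out WT LPS replicate 1 or 2 or KOKI replicate 1 or 2 gave 270, 311, 332 and 273. Prdm1, Xbp1, Jchain and Ell2 passed in each of these.

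Of 19 plasmablast genes, 11 rose, 0 fell and 8 did not pass, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 8.79e-21, and adjusted p = 0.0535 with an estimated correlation). Jchain, which joins IgM into polymers, went from 51.5 ± 10.1 to 308 ± 60.1 CPM (log2 2.58) and Ell2 from 57.6 to 150 CPM (log2 1.39). Of 20 unfolded protein response genes, 9 rose and 0 fell (13 adjusted over the list alone; camera adjusted p = 1.2e-08, and adjusted p = 0.124 with an estimated correlation), among them Creld2 (log2 1.00), the disulfide isomerase Pdia4 (log2 1.09) and the chaperone Hsp90b1 (log2 1.08). Without KOKI replicate 2, the library with Xist counts, 9 plasmablast genes and 1 unfolded protein response gene passed, all higher, and the medians went from log2 1.35 to 1.21 and from 0.65 to 0.62.

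Interferon response genes were lower. Of 25 tested, 15 fell, 0 rose and 10 did not pass, and 18 fell adjusted over the list alone (camera adjusted p = 2.72e-31, and adjusted p = 0.0535 with an estimated correlation); 11 fell without KOKI replicate 2. Rsad2 (viperin), an antiviral enzyme, went from 17.4 to 0.886 CPM (log2 −4.38), Ifit3 from 23.5 to 2.76 CPM (log2 −3.11) and Mx1, an antiviral GTPase, from 29.7 to 6.53 CPM (log2 −2.18). Oasl2 (chromosome 5, 114896936 to 114912234) had 0 counts in both KOKI cultures and 10.9 ± 3.20 CPM in WT, at least 163-fold lower. Slfn5 (log2 −3.32), the lipid carrier Apoe (log2 −2.88) and Nqo1, a quinone reductase (log2 −2.84), were also among the largest falls. Markers of other cells were lower alongside. T cell markers summed to 4.48 and 4.94 CPM in KOKI and 12.1 and 11.5 CPM in WT, with 0 of 12 passing, also adjusted over the list alone (camera adjusted p = 0.00225, and adjusted p = 0.229 with an estimated correlation). Of 8 macrophage and monocyte markers Lyz2 fell (log2 −1.41; 3 fell adjusted over the list alone; camera adjusted p = 0.0231, and adjusted p = 0.275 with an estimated correlation). Lyz2 did not pass without KOKI replicate 1 or without WT LPS replicate 1 (adjusted p = 0.0772 and 0.068).

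Part of the cholesterol synthesis and glycolysis genes was higher. Of 21 cholesterol synthesis genes, 11 rose, 0 fell and 10 did not pass, and 20 rose adjusted over the list alone (camera adjusted p = 2.41e-18, and adjusted p = 0.275 with an estimated correlation). Lss went up by log2 1.35 and Msmo1 by 1.01. Of 19 glycolysis genes, 6 rose and 0 fell, and 15 rose adjusted over the list alone (camera adjusted p = 3.21e-14, and adjusted p = 0.275 with an estimated correlation), led by the lactate exporter Slc16a3 (from 0.177 to 32.7 CPM, log2 7.43), the phosphofructokinase Pfkl (log2 1.53) and the glucose transporter Slc2a1 (log2 1.22). Of 34 cell cycle genes 5 rose, Mki67 among them (log2 0.80), and 7 did so adjusted over the list alone (camera adjusted p = 0.000111, and adjusted p = 0.275 with an estimated correlation). Without KOKI replicate 2 the counts were 3 cholesterol synthesis, 3 glycolysis and 0 cell cycle genes in edgeR, and the medians went from log2 0.89 to 0.72, from 0.88 to 0.52 and from 0.30 to 0.30. Mki67 did not pass without any 1 of the KOKI or WT LPS libraries.

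Of 25 mature B cell genes 3 fell, Fcmr (log2 −1.51), the egress receptor S1pr1 (a fall by log2 1.00) and Cd72 (log2 −0.68), and 6 fell adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.485 with an estimated correlation). Without KOKI replicate 2, 2 fell, and Cd72 did not pass without any 1 of the KOKI or WT LPS libraries. MHC class II genes were all 11 at a negative log2 fold change with 0 passing, also adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.275 with an estimated correlation). Of 24 NF-kB response genes Ccl22 rose (log2 1.11) while Tnf (log2 −1.05), Cd86 (log2 −0.93) and Cd69 (log2 −0.88) fell, 1 and 6 adjusted over the list alone (camera adjusted p = 0.0812), and 1 rose and 1 fell without KOKI replicate 2. Of the 25 lists 12 passed with the preset and 0 with an estimated correlation (fry called 8 for 1 direction and 23 mixed).

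Some of the largest differences were in genes with 0 counts in WT. Ccnb1ip1, a ubiquitin ligase of meiotic crossing-over (chromosome 14, 50789249 to 50795728), had 0 counts in both WT LPS cultures and 23.7 ± 2.44 CPM in KOKI, at least 433-fold higher. Rprl3, annotated as a ribozyme (chromosome 8, 3803069 to 3803358), had 0 counts in WT and 21.0 ± 2.74 CPM in KOKI, at least 373-fold higher. Rps13-ps1, a processed pseudogene of a ribosomal protein gene (chromosome 8, 87047689 to 87048226), stood at 363 ± 4.95 against 2.44 ± 0.137 CPM (log2 7.21, SE 0.17, edgeR adjusted p = 9.8e-07, n = 2 in each group). Eno1b (log2 6.15), Rpl34-ps1 (log2 5.11), Enpp4 (log2 4.16), Rps15a-ps6 (log2 4.07) and Prelid2 (log2 4.03) followed. Reads of pseudogenes can be shared with their parent genes, so the level of each is uncertain.

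Within the IgH locus KOKI cultures had higher Ighg3 and lower Ighg2b and Igha CPM than WT LPS cultures, while Ighm did not pass. KOKI is not spelled out in the labels, and strain variants of the locus, which could change how reads match mm10, were not tested. Counts of these genes and of the V segments below therefore need not follow the amount of RNA. Ighg3 rose from 11.4 ± 3.06 to 40.3 ± 2.62 CPM (log2 1.82, SE 0.20, edgeR adjusted p = 0.00334, n = 2 in each group). Ighg2b fell from 26.9 ± 0.584 to 10.0 ± 0.372 CPM (log2 −1.42, edgeR adjusted p = 0.00497, n = 2 in each group) and Igha from 9.16 ± 2.14 to 1.08 ± 0.317 CPM (log2 −3.11, edgeR adjusted p = 0.002, n = 2 in each group). Ighm was at 3110 ± 49.1 against 3060 ± 247 CPM (log2 0.02, SE 0.21), and its sign turned without WT LPS replicate 1 and without a low-count filter (log2 −0.06 and −0.02). Ighd (log2 −0.66, edgeR adjusted p = 0.0939) and Ighg2c (0 and 11 counts in KOKI against 71 and 201 in WT, log2 −4.18, edgeR adjusted p = 0.0764) passed adjusted over the IgH features alone (0.00962 and 0.00823). As a list, 7 IgH constant genes had 1 rise and 2 falls (1 and 4 adjusted over the list alone; camera adjusted p = 0.00378, and adjusted p = 0.395 with an estimated correlation). Without KOKI replicate 2 there were 1 rise and 3 falls.

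Summed IgH V segments were at 573 ± 51.3 CPM in KOKI and 883 ± 27.6 CPM in WT LPS cultures (log2 −0.62, SE 0.18), which did not pass in edgeR (adjusted p = 0.117; 0.0122 over the IgH features alone) and did in the DESeq2 Wald test (adjusted p = 0.00111). D segments (log2 −0.59) and J segments (log2 −0.26) did not pass. Of 104 single IgH V segments tested, 8 rose and 38 fell, among them Ighv1-64 (log2 −3.77, from 22.9 to 1.66 CPM), Ighv1-19 (log2 −4.80) and Ighv1-82 (log2 −3.91). Their direction went with position, which was looked up after the values were seen. The rise farthest from the constant genes was Ighv1-14, from 114646572 (log2 6.23). Every called segment beyond it, from Ighv1-15 (114657353) to Ighv1-85 (116000028), fell, while nearer segments went both ways. Among light chain features Igkc rose from 882 to 2070 CPM (log2 1.23, edgeR adjusted p = 0.0182), summed kappa V segments from 929 to 2130 CPM (log2 1.20, edgeR adjusted p = 0.0178), summed lambda V segments by log2 1.00 and Iglc1 by log2 1.01, and 37 of 102 kappa V segments rose while 0 fell. Iglc2 (log2 0.02), Iglc3 (log2 −0.11) and summed kappa J segments (log2 0.29) did not pass. As a list 2 of 5 light chain constant genes rose, also adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.275 with an estimated correlation), and 0 passed in edgeR without KOKI replicate 2. Igkc lost its call as well without KOKI replicate 1 or WT LPS replicate 1 (adjusted p = 0.0513 and 0.0799), and Iglc1 without any 1 of the KOKI or WT LPS libraries.

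**Figure D3:**
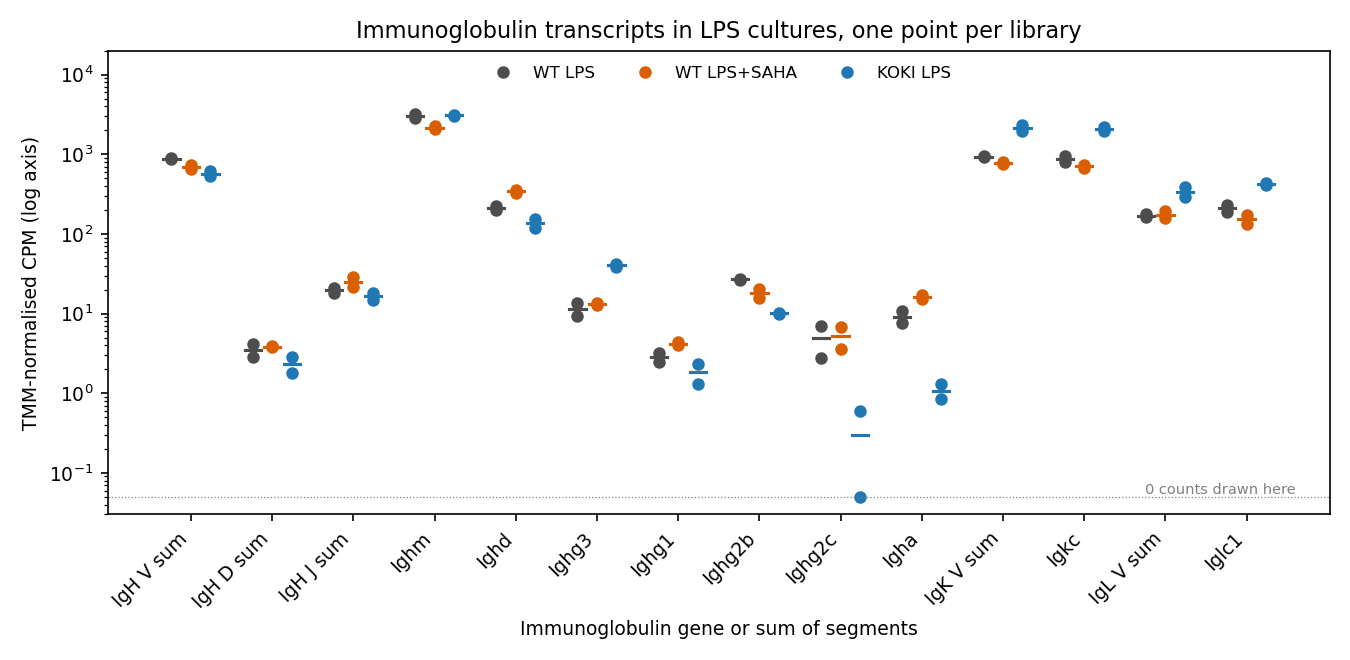
TMM-normalised CPM (log axis) of heavy and light chain genes and summed segments in the 6 splenic libraries, 1 point per library with a bar at the group mean. KOKI libraries lie above WT LPS for Ighg3, Igkc and kappa V segments and below for Ighg2b, Ighg2c and Igha.

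**Figure D4:**
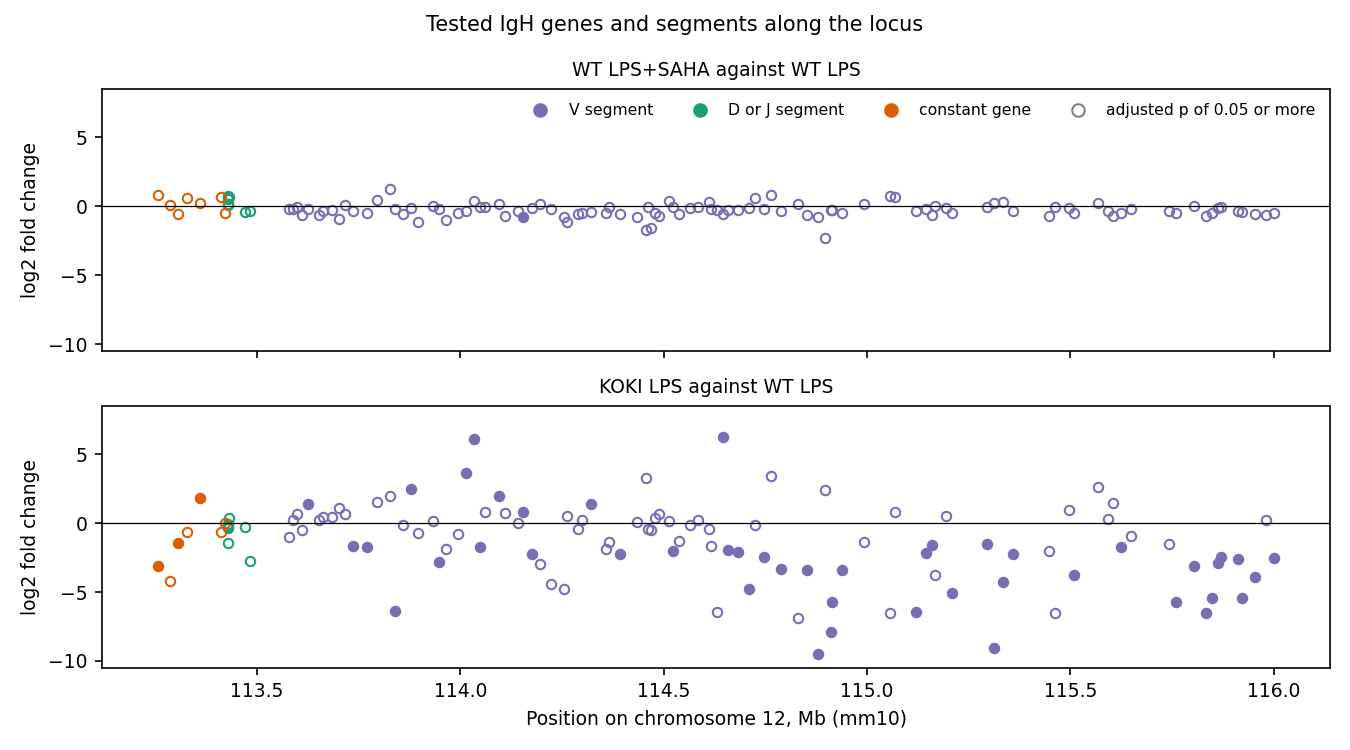
Log2 fold change of each tested IgH gene or segment against its position on chromosome 12 (mm10), for SAHA (upper panel) and KOKI (lower panel). Filled points passed an adjusted p of 0.05, as 38 V segments below 0 and 8 above did in KOKI cultures and 1 did with SAHA. Of the V segments that passed in KOKI cultures, all beyond Ighv1-14 (114646572) fell. Values of segments with 0 counts in a group depend on the prior count.

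The treatment label of the KOKI cultures names SAHA, so the SAHA and KOKI differences, both against the same WT LPS libraries, were set side by side. Across 15342 genes their log2 fold changes correlated at r = 0.053 (across genes, which are not independent replicates), where simulated unchanged groups against the shared libraries gave 0.489 (range 0.446 to 0.517 in 20 simulations). The simulations drew all libraries independently, whereas deviations of same-numbered WT LPS and WT LPS+SAHA libraries correlated at 0.51, which lowers the covariance that sharing gives (0.0453 here, 0.114 simulated). The simulated values are therefore too high a reference for paired libraries. With 1 WT LPS library for each comparison r was −0.177 and −0.141, and over genes with a mean of at least 10 CPM it was −0.102, so its sign depended on these choices. Of called genes, 9 rose in both (3.28 for independent lists) and 5 fell in both (10.4), 33 fell with SAHA and were higher in KOKI (12.7), and 17 rose with SAHA and were lower in KOKI (2.67). Prdm1 and Xbp1 were among those that moved apart.

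Set directly against WT LPS+SAHA, as the treatment label would pair them, the KOKI cultures differed in 3639 genes (2160 higher, 1479 lower, edgeR). Prdm1 was higher by log2 2.82, Xbp1 by 2.49, Jchain by 3.15 and Ccnb1 by 1.32, and Cr2 was lower (log2 −1.74), as was Gsn (log2 −0.98).

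In femoral cells 5 genes were higher and 0 lower in the 2 KOKI pools than in the 2 control pools, of 16624 tested (edgeR; 2687 at an unadjusted p under 0.05). Ifi44l, an interferon-induced gene (chromosome 3, 151758737 to 151762892), had 0 counts in both controls and 11.0 ± 6.67 CPM in KOKI, at least 227-fold higher (edgeR adjusted p = 0.0437, n = 2 in each group). Others were Rps3a3 (log2 5.11, from 8.31 to 287 CPM) and Rps3a2 (log2 2.58, from 18.9 to 114 CPM), both processed pseudogenes, and the predicted genes Gm13225 (log2 5.43) and Gm13160 (log2 1.81) on chromosome 4. In spleen, Rps3a3 stood at 297 and 8.34 TMM-normalised CPM in KOKI replicates 1 and 2, and at 5.89 and 7.78 in WT LPS. Rps3a2 stood at 132 and 29.4 there, and at 33.1 and 26.4 in WT LPS. Both pseudogenes were thus high in 1 of the 2 splenic KOKI cultures as well. The count was 0 with DESeq2 size factors in edgeR (adjusted p = 0.0515 for Ifi44l; 2702 genes at an unadjusted p under 0.05) and 0 in a fit of all 10 libraries (2796). It was 688 by the DESeq2 Wald test (456 higher, 232 lower), 662 without a low-count filter and 237 among protein-coding genes outside the immunoglobulin loci (192 and 45). Without control replicate 1 or 2 it was 2114 and 3456, and without the KOKI pool lacking both proteins or the one lacking RAG2 alone it was 39 and 13.

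Femoral lists moved in several lineages with 0 single members passing. The libraries differed in make-up between the same groups. Mitochondrial genes took 6.50 and 7.19% of counts in the controls and 3.50 and 3.57% in the KOKI pools, Rn7sk 2.93 and 3.62% against 6.83 and 8.56%, and histone genes 2.57 and 2.83% against 5.54 and 6.05%, so list changes are not separable from such differences. MHC class II genes were higher, all 11 with a positive log2 fold change (H2-Eb1, log2 1.00, edgeR adjusted p = 0.127) and 1 adjusted over the list alone (camera adjusted p = 0.00301). Stromal and endothelial markers were higher (camera adjusted p = 0.0142; 2 of 12 adjusted over the list alone), with Bglap, the osteoblast protein osteocalcin, at 192 ± 45.8 against 46.0 ± 19.3 CPM (log2 2.06, edgeR adjusted p = 0.0922, n = 2 in each group) and the collagen Col1a1 at log2 1.49. Summed, these markers took 756 and 1560 CPM in the controls and 2540 and 2380 CPM in the KOKI pools. Erythroid markers were lower (camera adjusted p = 0.00963; 3 of 15 adjusted over the list alone; Slc4a1, the red cell anion exchanger, log2 −0.85), as were interferon response genes (camera adjusted p = 0.00301; 2 higher and 8 lower of 25 adjusted over the list alone; Rsad2, log2 −1.05) and cell cycle genes (camera adjusted p = 0.046; 0 of 34 adjusted over the list alone; Mki67, log2 −1.17). Each of these 5 lists, of 27 tested, had an adjusted p = 0.747 with an estimated correlation, and fry called 0 lists for 1 direction and 2 mixed.

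No IgH feature passed between femoral KOKI and control pools in edgeR. Ighm was at 203 ± 33.1 against 178 ± 11.7 CPM (log2 0.19, edgeR adjusted p = 0.694, n = 2 in each group). Counts over the segments were few: 39 and 63 over all V segments in KOKI and 92 and 144 in the controls (log2 −0.64), 44 and 68 against 35 and 38 over D segments (log2 1.19, unadjusted p = 0.045, edgeR adjusted p = 0.299), and 239 and 243 against 455 and 519 over J segments (log2 −0.44).

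On the matched background, the KOKI pool lacking both proteins against the 2 controls, 0 of 20204 genes passed in edgeR (1660 at an unadjusted p under 0.05), and 19 did without control replicate 2. The smallest p values belonged to Ifi44l (0 counts in the controls), Dennd5b (log2 1.46), Bglap (log2 1.79), Gm26444 (log2 2.22) and St8sia6 (log2 −1.19), at edgeR adjusted p = 0.162 to 0.425. Between the KOKI pool lacking RAG2 alone and the one lacking both proteins 0 genes passed in edgeR (229 at an unadjusted p under 0.05), with Gimap4 (log2 −2.41), Sfn (log2 2.25) and Hspa1b (log2 −1.97) nearest. Both counts rose without a low-count filter, to 368 and 54. Each of these comparisons has 1 library in at least 1 arm, whose spread came from the other groups.

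The KOKI difference itself differed between spleen and femur for 171 of 20204 genes (edgeR test of the difference, 84 higher and 87 lower in spleen; 950 without a low-count filter). Xbp1 was among them (log2 difference 1.43, edgeR adjusted p = 0.0296), with log2 1.49 in spleen and 0.06 in femur, as were Ell2 and Mki67. Tissue went together with LPS culture, with the make-up of the cells and with the RAG2 and gamma c background. These differences therefore cannot be assigned to tissue. Genes within 10 Mb of the IgH locus, segments left out, were called at 4 of 99 with SAHA against 707 of 15125 (odds ratio 0.859, Fisher's exact p = 1), 3 of 99 in KOKI cultures against 574 of 15125 (odds ratio 0.792, Fisher's exact p = 1), each with an adjusted p of 1 over the 3 comparisons. In femoral cells edgeR called 5 genes in all, too few for this test, and 0 of 98 near the locus. Within 5 Mb the splenic odds ratios were 1.1 and 1.02, and within 20 Mb they were 0.749 and 1.13, so that their side of 1 depended on the window.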

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

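The tests of depth, of HDAC inhibition in every culture, of other lineages in the femoral libraries, of the sex of KOKI replicate 2, of the share on chromosome 12 and of the size of the femoral differences were chosen after the results they measure were seen; the remaining tests of the 3 patterns below were set before.

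The KOKI difference in spleen and the KOKI difference in femur were tested against each other in edgeR, and 171 genes differed between the tissues. The splenic cells were cultured with LPS, and the femoral pools lacked RAG2 and held RNA of other lineages. Tissue therefore cannot be told apart from these. Values that follow are the log2 difference in spleen minus that in femur. Most of the named genes had a large difference in the splenic cultures and a small one in femur. Ccnb1ip1 (12, SE 0.83), Rprl3 (13.45, SE 1.30), Slc16a3 (7.53, SE 0.67), Enpp4 (4.56), Prelid2 (4.27) and CAAA01093177.1 (4.22) were higher in splenic KOKI cultures. Oasl2 (−10.27, SE 0.90), Apoe (−3.16), Slfn5 (−2.84), Nqo1 (−2.67) and Rtp4 (−2.24) were lower there. Fitted values of Ccnb1ip1, Rprl3 and Oasl2 rest on a splenic group at 0 counts and depend on the prior count. Several copies of ribosomal protein and enolase genes rose in spleen and had smaller positive values in femur, Rps13-ps1 at 5.79 (log2 7.19 and 1.4), Rps15a-ps6 at 3.51 (4.05 and 0.55), Rpl34-ps1 at 3.50 (5.08 and 1.58) and Eno1b at 3.78 (6.13 and 2.36). Another ribosomal protein copy, Rps13-ps2, picked after its values were seen, went the other way, at −2.39 (−1.6 in spleen and 0.79 in femur). Rsad2 differed by −3.36 (log2 −4.42 in spleen and −1.05 in femur). Opposite signs were seen for Hist1h2bn, at −4.11 (log2 −2.81 in spleen and 1.29 in femur), for the predicted gene Gm13225, at −9.16 (−3.79 and 5.37), for the plasmablast gene Ell2, at 1.99 (1.36 and −0.63), for the proliferation gene Mki67, at 1.96 (0.78 and −1.18), and for Msmo1 of cholesterol synthesis, at 1.35 (0.99 and −0.36). Xbp1 differed by 1.43 (1.49 and 0.06). Adjusted p-values of these genes ran from 5.04e-05 (Rps13-ps1) to 0.0477 (Mki67).

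Olfactory receptor genes, which are silent in B cells, were detected in the SAHA cultures. Thinned to 18614742 counts, WT LPS+SAHA replicate 2 detected 34.1% of 1292 such genes and replicate 1 detected 9.52%, against 3.17% and 3.02% in the WT LPS libraries; depth does not account for this, since the lower SAHA library still detected 3 times as many as the higher WT LPS library. Opening of silent genes to 1 extent in every treated culture is argued against by the 3.59-fold gap between the SAHA libraries, although an effect that varies between cultures stays open. A candidate explanation is genomic DNA in the RNA: over genes with 0 counts in the femoral and KOKI libraries, counts per kb on the single X chromosome of replicate 2 were 0.489 of those on autosomes (bootstrap 0.434 to 0.55, 1576 X-linked and 17324 autosomal genes), near the ratio of their copies in male cells. The 3 other WT libraries had ratios of 0.488 to 0.556 at lower levels (0.184 to 0.452 against 1.29 autosomal counts per kb). Low transcription of silent genes in proportion to their copies would give the same ratio. The test therefore cannot tell DNA from such transcription, nor show how the cultures came to differ.

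Mature B cell transcripts were scarce in the libraries labelled femoral B cells. Over all 25 mature B cell genes the median femoral level was 0.03 of the splenic one (quartiles 0.000549 to 0.156, 3 genes higher in femur), whereas over 19 early B cell genes it was 9.98 times the splenic one (quartiles 1.16 to 22.6, 14 higher in femur), carried by genes such as Kit and Myb that blood progenitors also express, while Ebf1 (1.75 to 3.24 CPM), Vpreb3 (at most 0.26 CPM) and Blnk (12.3 to 21.1 CPM) were lower than in spleen. The lowest femoral library had 3030 times the neutrophil, 438 times the erythroid and 695 times the mast cell and basophil marker sum of the highest splenic one, with S100a8 at 3400 to 9170 CPM and Hba-a1 at 3340 to 5030 CPM, which is consistent with cells of other lineages in these libraries. Their share was not measured, no sort or gate is given in the labels, and an early stage of B cells without RAG2, which would lower mature B cell genes too, was not tested apart. A large part of the mast cell and basophil sum was Prg2, an eosinophil gene. Whether the pool labelled as lacking RAG2 alone held the same cells as the others stays open, since its sum over 12 pro-B and NK cell genes was 0.957 of the highest pool lacking gamma c as well, while the part from 5 NK cell genes was higher, as its label would have it (1.86 against 0.342 to 1.02 CPM).

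Large differences, some of them nearly all or none, set KOKI apart from WT cultures: 81 called genes outside the immunoglobulin loci had a log2 fold of at least 3 in size, 40 higher and 41 lower. Pseudogenes were over-represented among them (18 of 77 against 1076 of 14402, odds ratio 3.78, interval 2.09 to 6.52, Fisher's exact p = 1.27e-05), consistent with strain variants and reads shared with gene copies. The sex of KOKI replicate 2 is argued against as the main source, since a fit without it, of male-type libraries alone, called 59 such genes, 0.728 of the number with it (49 of them among the 81). DNA linked to the IgH locus is argued against for the 77 of these genes on other chromosomes. It stays open for the 4 on chromosome 12 (a share of 0.0494), of which 2 lay within 20 Mb (odds ratio 2.71, interval 0.32 to 10.3, Fisher's exact p = 0.175). The IgH genes and segments themselves were left out of the 81, so their differences were not weighed here. For a difference of the KOKI line shared by both tissues, 64 of the 81 genes could be looked up in femur. A share of 0.109 (7 of 64, 95% interval 4.51 to 21.2%) had the same sign and a log2 fold of at least 1 in size in the femoral KOKI pools. The same sign at any size was seen for 0.516 (33 of 64, interval 38.7 to 64.2%, exact binomial p = 0.901). Most of these differences thus did not recur at that size in the femoral pools. The femoral mice have another background and their libraries held little mature B cell RNA, so a difference of the KOKI line stays open.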

How the results depend on the processing

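Alternatives using normalisation without ribosomal RNA, 7SK and satellite genes, protein-coding genes outside the immunoglobulin loci alone, and list members without 1 doubted library were chosen after seeing the data; the others were planned. Over 165 named genes and their alternatives, 2254 values in all, 1727 kept their direction and side of the threshold, 421 kept their direction and lost the threshold, 92 gained it and 14 changed sign. All 712 genes called with SAHA kept their direction in every alternative that tested them, as did all 626 splenic KOKI genes, except that 623 did against WT LPS+SAHA. These genes were picked from libraries that the alternatives use again, which by itself favours the same direction. Depth was 18614742 to 29314068 counts, which left the femoral IgH segments with few counts. Except where given, the cause of a change was not tested.

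Genes changed by SAHA (712) numbered 1721 by DESeq2, 1970 without a low-count filter (all-gene median log2 moved to 0.54), 0 to 290 when 1 library was left out (in edgeR, at least 2650 unadjusted where 0), 211 with all 10 libraries and 0 with only the 4 compared (edgeR, 3765 unadjusted; fewer samples). They numbered 3413 with the replicate block (the same 4 libraries, 1 residual degree of freedom) and 1346 among protein-coding genes. RLE factors, normalisation without immunoglobulin genes and normalisation without ribosomal RNA gave 580, 737 and 550. The higher share was 20.5%, and 32.4% by DESeq2, 36.3% with the block and 38.7% among protein-coding genes. Splenic KOKI calls (626) numbered 1097 by DESeq2, 1254 without a filter, 270 to 708 when 1 library was left out and 3639 against WT LPS+SAHA. Femoral KOKI calls (5) numbered 0 with RLE factors (2702 at an unadjusted p under 0.05 in edgeR), 688 by DESeq2, 662 without a filter, 13 to 3456 when 1 library was left out, 0 with all 10 libraries (2796 unadjusted), 2 with 3 groups and 237 among protein-coding genes. On the matched background (0 in edgeR, 1660 unadjusted) calls were 368 without a filter, 1 with the 4 femoral libraries and 0 to 19 without 1 control. Without a filter the femoral KOKI pools differed in 54 genes (0 in edgeR with it, 229 unadjusted) and the tissues in 950 (171). With an estimated correlation 0 lists passed in each main comparison, against 9, 12 and 5 with the preset (fry called 9, 8 and 0).

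For pairing, the replicate block changed no call of the SAHA results given here other than those printed beside them, the 3413 above, the blocked list counts, and H1f0, Lyz2 and Pax5, which gained one (adjusted p = 0.0156, 0.00191 and 0.0277). WT and KOKI cultures share only a number (deviations correlated at 0.18), as do femoral controls and KOKI pools (−0.032); there the block gave 1313 and 869 genes, and for the summed V segments log2 −0.63 (adjusted p = 0.0151). DESeq2 also called these (log2 −0.62).

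Signs turned as follows. With SAHA, leaving out 1 library gave ranges of −0.02 to 0.50 for Ighg3, −0.47 to 0.88 for Ighg2c and −0.13 to 0.44 for the D segments. In KOKI cultures Ighm ranged from −0.06 to 0.10, with −0.02 without a filter and 0.00 with all 10 libraries, and Il2rg from −0.14 to 0.04. In femoral cells the ranges were 0.00 to 0.14 for Xbp1, −0.08 to 0.32 for Irf4, −0.03 to 0.59 for Il2rg, −0.65 to 0.24 for Bach2 and −0.01 to 0.44 for Rag2. None of these had passed. The correlation of the SAHA and KOKI differences (0.053) was −0.102 over genes of at least 10 CPM and −0.177 and −0.141 with split controls. Odds ratios near the IgH locus crossed 1 at 5 Mb (1.1 with SAHA, 1.02 in KOKI) and at 20 Mb in KOKI (1.13).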

Other observations

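The values in this part were looked up only after the data were seen. Of 712 genes called with SAHA, 433 (60.8%) had the opposite sign in KOKI cultures, with 349 of 566 that fell being higher in KOKI and 84 of 146 that rose being lower, while their log2 fold changes correlated at r = −0.00215. Both differences share the WT LPS libraries, which by itself favours the same sign, less so for paired libraries.

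Transcripts of the satellite-containing genes Gm10800 and Gm26870 took 1.66% and 7.40% of counts in the WT LPS libraries, 5.50% and 8.71% in the SAHA libraries, 0.63% and 0.43% in the KOKI cultures and at most 0.0751% in the femoral libraries. WT LPS+SAHA replicate 2 had counts on 31524 genes, and the other splenic libraries on 17957 to 22237. Within the IgH locus, Ighv1-36 and Ighv1-58 had 0 counts in both KOKI cultures and 3.82 and 2.89 CPM in WT. NK cell and ILC markers summed to 98.4 to 115 CPM in the femoral libraries and 2.07 to 6.18 CPM in the splenic ones. The NK cell genes Ncr1, Gzma, Klrb1c, Eomes and Prf1 together gave only 0.342 to 1.86 CPM in the femoral libraries. Most of the list sum thus came from other genes, and it does not show NK cells there.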
